A study of Macaca mulatta with 20 samples.

How the data were processed

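RNA was measured in 4 cell populations sorted from peripheral blood mononuclear cells of 5 adult female rhesus macaques, with 1 array for each population of each animal and 20 arrays in all. Per the labels, total RNA was extracted with Qiagen RNeasy columns and DNase treatment, its quality was read on an Agilent Bioanalyzer, and biotin-labelled cRNA for Illumina arrays was made with the Ambion MessageAmp kit. The submitters' processing notes name the R package lumi with no version, steps or parameters. The background correction, the filter that led to the 7303 probes in the table, the treatment of repeated beads and the gate used for sorting are not given in the sources used here.

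The deposited values are on a log scale and were used as log2, since they run from 7.50 to 14.77. All 20 columns hold the same distribution, with a median of 8.39 and quartiles of 8.04 and 9.21, and their sorted values differ by at most 0.000913, so the authors had normalized them to a common distribution. Of the 2 deposited tables, 1 is named as not normalized, yet the 2 are identical value by value, so raw intensities were not used here. The base of the logarithm is not stated. The variance-stabilised scale that lumi offers cannot be told apart from log2 in these values. On that scale the differences of dim probes would be smaller than on log2, and every difference called log2 carries that limit. The arrays hold human probes, so the level of a probe depends on how well it matches the macaque transcript, and each probe was compared only with itself. Detection p-values were not used here, and the precision of each value is limited by the number of arrays.

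Probes were named through the platform annotation of the array, with the symbols as that table gives them. This gave 6055 probes with 1 symbol, 1 probe with several and 1247 without a name, which were tested and counted but not named. The 6055 probes stand for 5236 symbols, of which 701 have several probes, and 4940 of the symbols also occur in the RefSeq gene table of the rhesus macaque. Coordinates were not used here. Probes for gene families with near-identical members, such as CCL3L3, the class II HLA genes, the globins and the metallothioneins, were not assigned to a single member by the arrays. A gene with several probes is described by the probe with the highest mean over the 20 arrays.

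Each array was placed in its group by its label. The replicate number is the dominance rank of the animal, where 1 is high and 5 is low, and the animal code in the titles shows that the 4 arrays of a rank come from 1 animal. Deviations from the cell type means had a median correlation over probes of 0.380 between arrays of the same animal (0.0156 to 0.863 in 30 pairs) and of -0.0716 between arrays of different animals and types. Each rank is held by 1 animal, and the animals came from 5 social groups, so rank, animal and social group cannot be told apart.

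Cell types were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of all 20 arrays with the animal as a block, and p-values were adjusted by the Benjamini-Hochberg method within each of the 6 pairwise contrasts, with a threshold of 0.05. A probe was called enriched in a cell type when it was higher than in each of the other 3, with an adjusted p under 0.05 and a difference of at least 1 log2 in all 3 contrasts. Rank was tested as a slope per rank step over the 5 arrays of each cell type and over the mean of each animal's 4 arrays, where a positive slope means higher in lower-ranking animals. An F test of the interaction of cell type and rank, with the animal as a block, asked whether the slope differs between cell types. Errors are standard errors of the fit (SE) unless named as SD, and all tests were two-sided.

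A set of 24 gene lists was fixed from textbook knowledge. They are markers of T cells, helper T cells, monocytes, B cells, NK cells, platelets, red blood cells (erythroid), granulocytes, dendritic cells and plasma cells, cytotoxic T cell and NK effector genes, MHC class II genes, T cell receptor signalling, B cell receptor signalling, Toll-like receptor genes, lineage transcription factors, chemokine receptors and homing genes, type I interferon genes, inflammatory genes, glucocorticoid-responsive genes, immediate early genes, heat shock genes, cell cycle genes and cytosolic ribosomal protein genes. Some genes stand in more than 1 list, such as CD79B and CD72 in both B cell lists, LAT and ZAP70 in both T cell lists, and CD14 and TLR4 in the monocyte and Toll-like receptor lists. For each list and cell type, members were counted in the contrast of that type against the mean of the other 3, and limma's camera compared the list with all other probes, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists and cell types. For 8 lists the slope of the list mean on rank was tested by an exact permutation of the 5 ranks over all 120 orders, adjusted over 40 tests. The smallest p this can give is 0.0167, so no list can pass after adjustment unless a large part of the 40 tests reach that value.

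The rule for named genes took, for each cell type, the 7 enriched genes whose smallest of the 3 differences is largest, up to 12 genes per direction between helper and cytotoxic T cells with the same direction in all 5 animals, the 3 genes with the smallest p in each rank fit where none passed, the 3 with the smallest p for the interaction, up to 4 members per list with the largest change, and NR3C1, PTGS2, CXCR2 and NFATC1 for rank. The groups, contrasts, fits, lists, this rule and the alternatives were set before the data were examined. The alternatives were other normalizations, a filter on dim probes, 1 probe per gene, other moderation, array weights, no block or a random block, only the 10 arrays of a contrast, no minimum difference, pooled slopes, a range filter of 0.2, rank as high against low, other list summaries, and leaving out each animal in turn. Fits without the cytotoxic T cell and B cell arrays of the rank 4 animal (18 arrays) were added after seeing that these 2 arrays stood apart.

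The code was tested on simulated data made from the real spread of the 7303 probes. With the spread of all 20 arrays, the contrast of helper against cytotoxic T cells recovered 22% of 50 probes changed by 0.5 log2, 70% at 1, 90% at 2 and 98% at 4, and 17 of its 157 calls were unchanged probes, more than the threshold of 0.05 allows on average. With the spread of the 18 arrays, again drawn for 20 arrays, it recovered 76%, 96%, 100% and 100%, with 9 unchanged probes among 195 calls. The simulations of probes drew noise apart for each probe, with the same spread in every array. In the real data the extra spread lies in 2 arrays, so these rates test the code and need not hold for the real fits. Slopes of 0.5 log2 per rank step were recovered for 82% of 50 probes in helper T cells, 90% in monocytes, 18% in cytotoxic T cells, 18% in B cells and 38% in the mean of the 4 types. For the interaction, slopes placed in monocytes were recovered for 38% of 50 probes at 0.5 log2 per step and 74% at 1. The permutation test of list slopes gave p under 0.05 for 3.75% of 2000 simulated lists without an effect.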

Results

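Gene expression was profiled in monocytes, B cells, helper T cells and cytotoxic T cells from the blood of 5 adult female rhesus macaques, which held dominance ranks 1 (high) to 5 (low) in 5 different social groups. Each population was measured in each animal, giving 5 arrays per cell type and 20 arrays in all. The title of the series asks how social behavior bears on gene regulation, and this part of it resolves expression by cell type. The design allows 2 kinds of comparison. Cell types can be compared within animals, and each gene can be followed along rank within a cell type, with 1 animal per rank.

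The sorted populations carried the transcripts of their lineage in 18 of the 20 arrays. CD3D, a chain of the T cell receptor complex, lay between 12.99 and 14.06 log2 in the 5 helper arrays and in the cytotoxic arrays of ranks 1, 2, 3 and 5. In monocytes it lay between 7.63 and 7.75. CD79B, a chain of the B cell receptor complex, lay between 13.15 and 13.90 in the B cell arrays of ranks 1, 2, 3 and 5. CD14, the lipopolysaccharide co-receptor, lay between 12.14 and 14.16 in monocytes. In the cytotoxic T cell array of the rank 4 animal CD3D was at 7.87 and CD8A at 8.12. In the B cell array of the same animal CD79B was at 8.36. Those 2 arrays correlated with each other over probes (r = 0.876) but only at 0.148 to 0.193 with the other 18. Among the other 18, arrays of the same type correlated with a median of 0.938 or more. B2M, the light chain of MHC class I, was at 8.07 and 8.44 in these 2 arrays and between 12.62 and 13.49 in the other 18. By contrast CAMTA1 (14.08 and 14.66) and PDGFA (13.57 and 13.87) were bright in them and at most 8.77 elsewhere. Since all columns share 1 distribution, a bright value gives the place of a probe within its array and not the amount of RNA. CD3D was at 9.74, 9.41, 10.32 and 11.17 in the B cell arrays of ranks 1, 2, 3 and 5, against at most 7.75 in monocytes. CD3G was higher there too, at 9.12, 8.23, 9.93 and 9.98 against at most 7.93 in monocytes. The other T cell genes were mixed. CD6, CD2, BCL11B and CD8A had higher means there, at 8.45, 8.34, 8.01 and 9.38 against 7.63, 7.99, 7.64 and 8.21 in monocytes. Their SD in these B cell arrays was 0.314, 0.369, 0.275 and 1.217. CD3E, LAT and IL7R were about level. CD3E was at most 7.84 there and 7.83 in monocytes. LAT and IL7R had means of 7.66 and 8.04 there and of 7.71 and 8.03 in monocytes. CD8A was at 10.62, 10.72, 9.50, 8.31 and 11.29 in the helper arrays of ranks 1 to 5, where CD8B was at most 8.01. All 20 arrays entered the fits as designed, and the counts of probes and the calls of gene lists are also given for the 18 arrays without these 2.

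**Figure D1:**
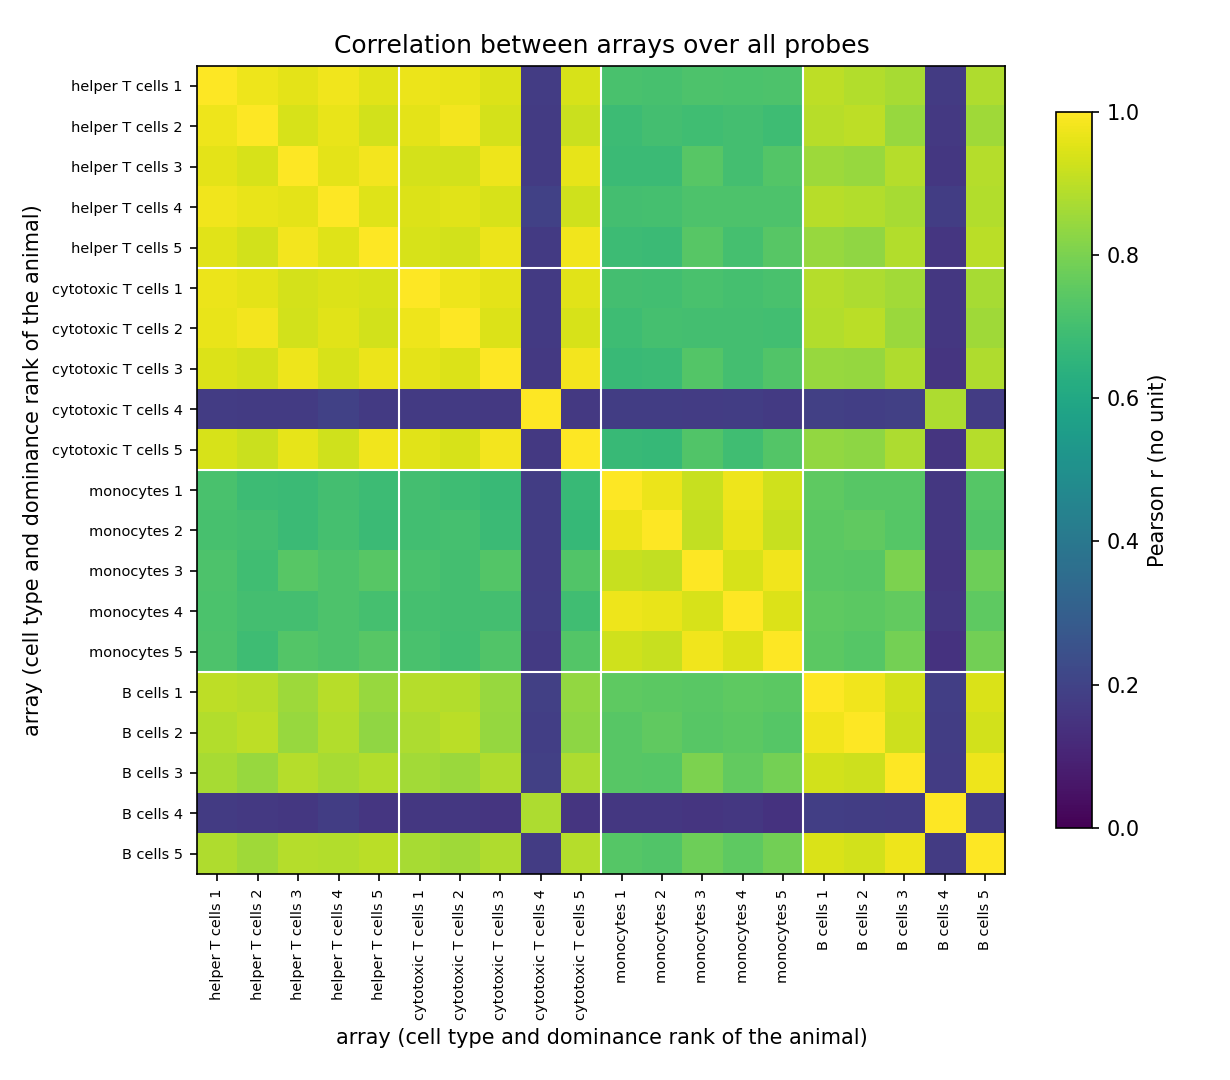
Pearson correlation over all probes between each pair of the 20 arrays, ordered by cell type and by rank 1 to 5 within it, with the colour scale giving r. The cytotoxic T cell and B cell arrays of the rank 4 animal correlate with each other (0.876) and at 0.148 to 0.193 with the other 18.

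**Figure D2:**
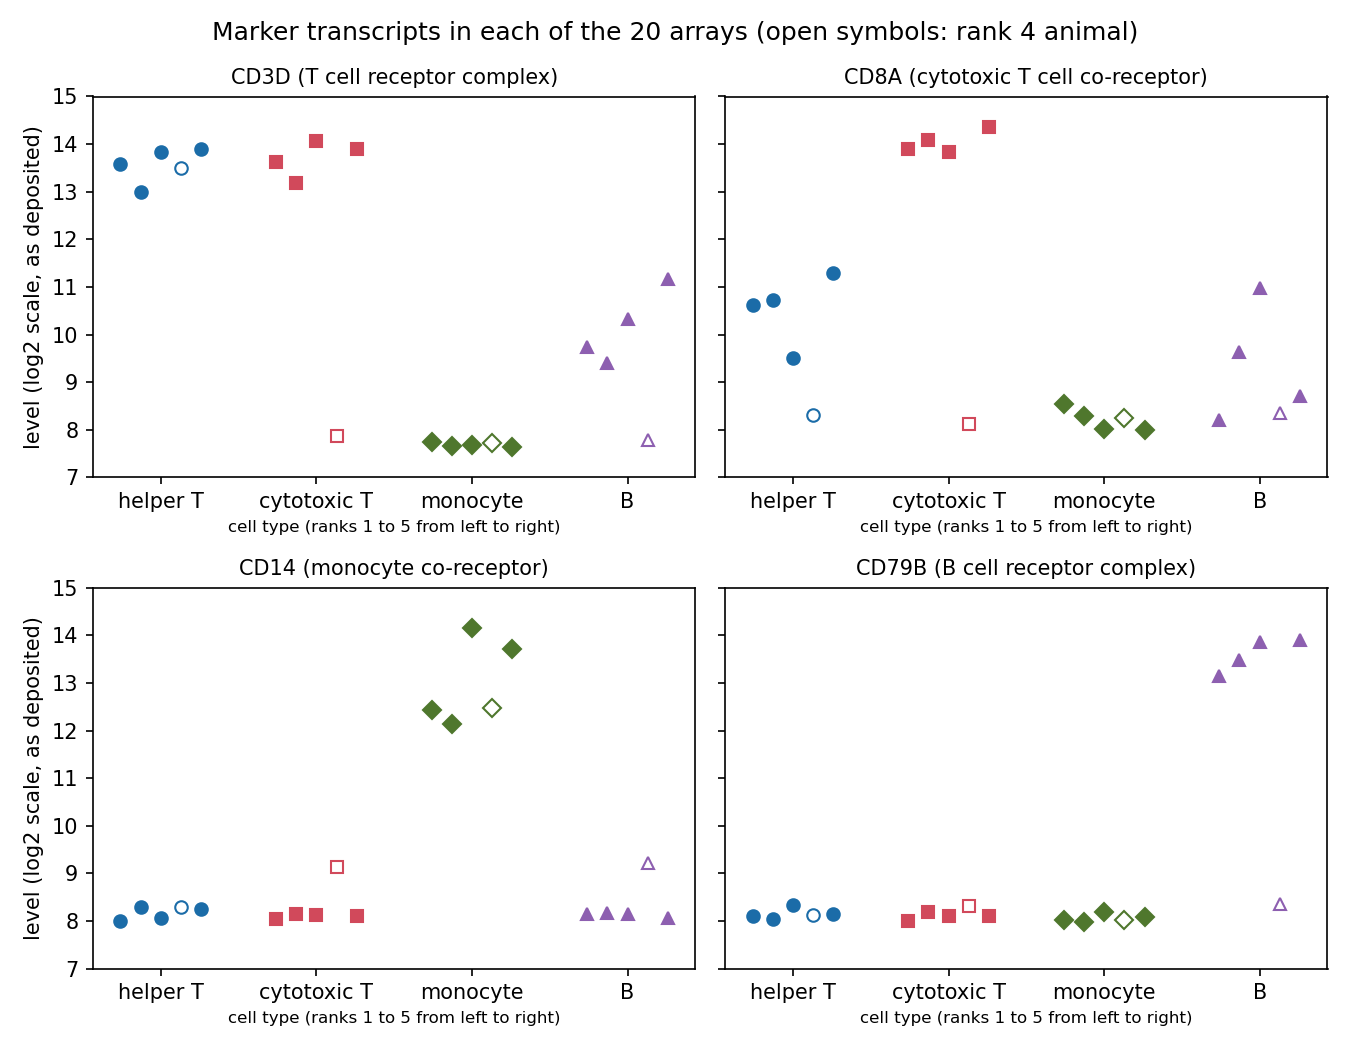
Levels (log2) of CD3D, CD8A, CD14 and CD79B, 1 point per array, by cell type, with open symbols for the rank 4 animal. CD3D is at 7.87 in the rank 4 cytotoxic T cell array and CD79B at 8.36 in the rank 4 B cell array, at the level of the types that lack them.

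Monocytes had more enriched probes than any other type, led by S100A9 and CST3. S100A9, a calcium-binding protein of myeloid cells, was higher than in the nearest other type by 6.02 ± 0.17 log2 (n = 5 animals, adjusted p = 5.23e-12), with means of 14.21 ± 0.40 (SD) in monocytes and at most 8.18 in the others. CST3, a secreted protease inhibitor, was higher by 5.97 ± 0.11, CAMP, an antimicrobial peptide precursor, by 5.83 ± 0.12, and HBEGF, a growth factor, by 5.67 ± 0.14. CPVL, a carboxypeptidase of macrophages, was higher by 5.27 ± 0.11, and the chemokines CCL3L3 and CXCL8 by 5.18 ± 0.17 and 5.15 ± 0.24. In all, 360 probes, 292 of them named, were enriched in monocytes. Without the 2 rank 4 arrays 366 were, of which 327 were shared, and AIF1 (5.60 ± 0.08), a protein of the monocyte lineage, then ranked among the first 7. Leaving out any 1 animal gave 330 to 368.

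In B cells the enriched genes were led by the antigen receptor. CD79B was higher than in the nearest other type by 4.40 ± 0.70 log2 (n = 5, adjusted p = 0.00251), and by 5.43 ± 0.10 (adjusted p = 1.05e-12) without the rank 4 B cell array, in which it was at background. LDB2, a LIM domain binding protein, was higher by 2.64 ± 0.38, RAB30, a small GTPase, by 2.20 ± 0.37, and MTSS1, an actin-binding protein, by 2.16 ± 0.33. KBTBD8 (2.06 ± 0.40), KCNIP3 (1.93 ± 0.37), a calcium-binding protein, and XKRX (1.85 ± 0.32) followed. With 18 arrays TOX2, a transcription factor of lymphocytes, was higher by 2.72 ± 0.27 and GGA2, a Golgi sorting adaptor, by 2.42 ± 0.17. TOX2 has 3 probes, of which 2 were enriched. Of the 48 probes enriched in B cells, 40 were named. The count was 76 without the 2 rank 4 arrays, 46 of them shared, and 15, 25, 14, 76 and 20 without the animal of rank 1, 2, 3, 4 and 5. CD79B and RAB30 missed the threshold without rank 1 or 3, KCNIP3 also without 5, and KBTBD8 and XKRX without any 1 of ranks 1, 2, 3 and 5.

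Among T cells, helper cells were marked by TRIB2 and AXIN2 and cytotoxic cells by a chain of CD8. In helper T cells TRIB2, a pseudokinase, was higher than in the nearest type, cytotoxic T cells, by 1.42 ± 0.23 log2 (n = 5, adjusted p = 0.0162) and AXIN2, a feedback inhibitor of Wnt signalling, by 1.18 ± 0.17 (adjusted p = 0.011). In cytotoxic T cells CD8B, a chain of the CD8 co-receptor, was higher than in B cells by 1.08 ± 0.16 (adjusted p = 0.00877). With 18 arrays the helper list also held APOD (1.74 ± 0.33), a lipocalin, LEF1 (1.39 ± 0.27), a transcription factor of the Wnt pathway, and SPOCK2 (1.01 ± 0.12), a matrix proteoglycan. LEF1 has 2 probes, of which only 1 was enriched. The cytotoxic list then opened with CD8A (3.74 ± 0.55), the chemokine CCL5 (3.34 ± 0.32) and KLRD1 (2.72 ± 0.26), the CD94 receptor of killer cells. GNLY (2.59 ± 0.31), GZMK (2.30 ± 0.26) and GZMH (1.94 ± 0.27), proteins of cytotoxic granules, and EOMES (2.16 ± 0.11), a transcription factor of effector cells, followed. With 20 arrays 5 probes were enriched in helper T cells (2 named) and 1 in cytotoxic T cells, and with 18 arrays 8 and 22, which included all 5 and the 1. Leaving out rank 1, 2, 3, 4 or 5 gave 0, 3, 0, 8 and 0 probes in helper and 0, 0, 0, 22 and 0 in cytotoxic T cells. TRIB2 held without rank 2 or 4, and AXIN2 and CD8B only without rank 4.

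Compared directly, helper T cells expressed more CD4 and cytotoxic T cells more CD8. CD4, the co-receptor for MHC class II, was higher in helper cells by 0.78 ± 0.12 log2 (adjusted p = 0.0162) and CD8B lower by 1.20 ± 0.16 (difference -1.20, adjusted p = 0.00877), each in 5 of 5 animals. The rank 4 pair lends this no support, since CD8B was at 8.58 in its cytotoxic array and at 8.56 in the B cell array of the same animal. SEPTIN3, a cytoskeletal GTPase, had the smallest adjusted p, with a difference of 1.30 ± 0.11 (adjusted p = 7.18e-05). Beside TRIB2 and AXIN2, higher levels in helper cells were found for GALT (0.95 ± 0.16), an enzyme of galactose metabolism, RCAN3 (0.92 ± 0.16), a calcineurin regulator, and LDOC1 (0.77 ± 0.12). The same was found for KLHL5 (0.65 ± 0.10), TRAF3IP2 (0.62 ± 0.12), an adaptor of interleukin 17 signalling, PTPN13 (0.60 ± 0.11), a phosphatase, SOS1 (0.58 ± 0.11), a Ras activator, and KLF8 (0.56 ± 0.11). DUSP22 (-0.44 ± 0.07), a phosphatase that restrains T cell receptor signalling, was the other gene lower in helper cells. GALT, KLHL5 and DUSP22 have 2 probes each, of which only 1 passed. By limma 22 probes differed, 19 of them higher in helper cells, and 13 and 2 named genes met the rule.

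Without the 2 rank 4 arrays the same contrast was led by CD8A and CCL5 on the cytotoxic side. The fit without them kept the helper and monocyte arrays of the rank 4 animal, and 4 animals had both T cell arrays. In this fit CD8A differed by -3.74 ± 0.55 log2, CCL5 by -3.34 ± 0.32, KLRD1 by -2.72 ± 0.26 and GNLY by -2.59 ± 0.31. Also lower in helper cells were GZMK (-2.30 ± 0.26), EOMES (-2.16 ± 0.11), GZMH (-1.94 ± 0.27) and CST7 (-1.88 ± 0.27), a protease inhibitor of killer cells. So were LAG3 (-1.87 ± 0.13), an inhibitory receptor, SPRY2 (-1.81 ± 0.38), GZMA (-1.79 ± 0.24) and PRSS57 (-1.61 ± 0.23). The genes of the helper side held APOD (1.75 ± 0.36), SEPTIN3 (1.42 ± 0.08), LEF1 (1.39 ± 0.27), and CTSH (1.23 ± 0.16), a lysosomal protease. They also held TRIM8 (1.08 ± 0.19), SPOCK2 (1.01 ± 0.12), TRIB1 (0.98 ± 0.18), STK24 (0.91 ± 0.22), INPP4B (0.91 ± 0.15), a phosphoinositide phosphatase, and DPEP2 (0.88 ± 0.15). CTSH and STK24 have 2 probes each, of which only 1 passed. The count rose to 193 probes, 88 higher and 105 lower in helper cells, among them all 22 of the first fit in the same direction. Leaving out the animal of rank 1, 2, 3, 4 or 5 gave 2, 11, 1, 140 and 3 probes. Only the 10 arrays of the 2 types with the replicate block gave 0 by limma, with 395 at an unadjusted p under 0.05. All genes named for this contrast with 20 arrays except SEPTIN3 missed the threshold without rank 1, 3 or 5, and AXIN2, GALT, CD4, TRAF3IP2, PTPN13, SOS1, KLF8 and CD8B also without rank 2.

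The other contrasts counted more probes, and most of them parted monocytes from lymphocytes. CST3, S100A9 and CAMP lay on the monocyte side of each monocyte contrast and CD79B on the B cell side of each B cell contrast. Between helper T cells and monocytes 2591 probes differed, 1458 higher in helper cells. Between cytotoxic T cells and monocytes 2361 did, 1238 higher in cytotoxic cells. Monocytes and B cells differed in 2086, of which 1051 were higher in monocytes. Helper T cells and B cells differed in 671 (395 higher in helper cells) and cytotoxic T cells and B cells in 462 (237 higher in cytotoxic cells). Without the 2 rank 4 arrays the counts were 4488, 4328, 3914, 1839 and 1819 in the same order, and they held 2591, 2348, 2072, 669 and 461 of the first calls, all in the same direction. Leaving out the rank 4 animal gave 4220, 4270, 3847, 1744 and 1808. Monocytes against B cells gave 1290 without rank 1 and 1371 without rank 2. Helper T cells against B cells gave 313, 330, 281 and 306 without rank 1, 2, 3 and 5, and cytotoxic T cells against B cells 69, 136, 73 and 93.

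Gene lists were compared between each cell type and the mean of the other 3, and 38 of the 96 combinations passed with limma's camera. With 18 arrays 39 did, 34 of them shared. Each contrast sets 1 type against the mean of the other 3, so a list high in 1 type alone tends to come out lower in the others. Calls of 1 list in several types are therefore not separate results. The list of monocyte markers was called in all 4 types. In monocytes 12 of 12 measured genes were higher (12 adjusted over the list alone, adjusted p = 2.69e-13). Its largest differences were CST3 at 6.29 ± 0.09 log2, S100A9 at 6.14 ± 0.14, CD14 at 4.71 ± 0.27 and FCER1G, an adaptor of Fc receptors, at 4.36 ± 0.12. The same list was lower in helper T cells (9 of 12, 11 over the list alone, adjusted p = 4.16e-12), cytotoxic T cells (8, 9 over the list alone, adjusted p = 3.45e-12) and B cells (7, 9 over the list alone, adjusted p = 1.55e-10). Toll-like receptor genes were higher in monocytes (7 of 12, 7 over the list alone, adjusted p = 0.000806), with TLR4 at 3.01 ± 0.06 and TLR8 at 1.34 ± 0.10. They were lower in helper (6, 8 over the list alone, adjusted p = 0.000341) and cytotoxic T cells (4, 4 over the list alone, adjusted p = 0.00142). These 7 calls and the lineage transcription factors in B cells were the 8 that held with an estimated correlation. Their adjusted p values with 20 arrays and an estimated correlation were 0.0311 in monocytes, 0.0311 in helper T cells, 0.0311 in cytotoxic T cells and 0.0392 in B cells for the monocyte markers. For the Toll-like receptor genes they were 0.0311, 0.0311 and 0.0324 in monocytes, helper and cytotoxic T cells. With 18 arrays 14 held, 7 of them shared, and the monocyte markers in B cells did not (adjusted p = 0.0703). In the rank 4 cytotoxic T cell array the monocyte marker list averaged 8.38, against 7.79 to 7.88 in the other cytotoxic arrays.

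Other myeloid and stimulus-response genes were also higher in monocytes. Of 8 granulocyte markers 4 were higher (4 over the list alone, adjusted p = 0.00151, and adjusted p = 0.0955 with an estimated correlation), with CAMP at 5.85 ± 0.09 and CSF3R, the receptor of the neutrophil growth factor G-CSF, at 4.97 ± 0.15. Among 8 inflammatory genes 4 were higher, led by CXCL8 (5.28 ± 0.20) and PTGS2 (3.05 ± 0.19), the inducible cyclooxygenase (4 over the list alone, adjusted p = 0.0308, and adjusted p = 0.352 with an estimated correlation). The inflammatory call was lost without the rank 4 animal and with 18 arrays (adjusted p = 0.118). Of 10 immediate early genes, which respond within minutes to stimuli, 6 were higher, with FOSB at 2.71 ± 0.34, PPP1R15A at 2.69 ± 0.50 and EGR1 at 2.28 ± 0.34 (6 over the list alone, adjusted p = 0.0241, and adjusted p = 0.208 with an estimated correlation). Lower in monocytes were 10 of 12 T cell markers (10 over the list alone, adjusted p = 0.000112, and adjusted p = 0.208 with an estimated correlation). The same held for 11 of 14 cytotoxic and NK effector genes (12 over the list alone, adjusted p = 0.00896, and adjusted p = 0.59 with an estimated correlation). It also held for 4 of 7 T cell receptor signalling genes (5 over the list alone, adjusted p = 0.0398, and adjusted p = 0.326 with an estimated correlation). Of the cell cycle genes 4 of 6 were lower, such as MCM6 at -0.72 ± 0.08 (4 over the list alone, adjusted p = 0.0247, and adjusted p = 0.187 with an estimated correlation). The cell cycle call was lost without rank 4 and with 18 arrays (adjusted p = 0.0932), and the T cell receptor signalling call without rank 2 or 5.

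Helper T cells carried the T cell lists. Of 12 T cell markers 10 were higher (10 over the list alone, adjusted p = 3.41e-10, and adjusted p = 0.0877 with an estimated correlation), with CD3D at 3.59 ± 0.61 log2, CD6 at 3.34 ± 0.37, IL7R, the interleukin 7 receptor, at 3.10 ± 0.37 and CD2 at 2.65 ± 0.38. Of 5 helper T cell markers CD4 (0.65 ± 0.10) and CTLA4 (0.53 ± 0.07), an inhibitory receptor, were higher and the other 3 did not pass (2 over the list alone, adjusted p = 0.0115, and adjusted p = 0.0877 with an estimated correlation). Of 7 T cell receptor signalling genes 4 were higher, led by LAT (2.51 ± 0.35), FYN (1.91 ± 0.27) and ZAP70 (1.46 ± 0.24) (4 over the list alone, adjusted p = 0.0161, and adjusted p = 0.247 with an estimated correlation). Of 6 cell cycle genes CDC20 (0.47 ± 0.08) and MCM6 (0.35 ± 0.08) were higher (3 over the list alone, adjusted p = 0.0223, and adjusted p = 0.186 with an estimated correlation), a call lost without rank 3. Lower were 3 of 8 granulocyte markers (3 over the list alone, adjusted p = 0.000699, and adjusted p = 0.0877 with an estimated correlation). So were 3 of 4 MHC class II genes (3 over the list alone, adjusted p = 0.0124, and adjusted p = 0.187 with an estimated correlation), with CD74, the invariant chain, at -2.92 ± 0.50. With 18 arrays 4 of 5 helper T cell markers were higher (5 over the list alone) and all 12 T cell markers, the latter also passing with an estimated correlation (adjusted p = 0.0489). With 18 arrays 3 lists more passed in helper T cells. They were the B cell markers (3 of 6 lower and 1 higher, adjusted p = 0.029), the B cell receptor signalling genes (3 of 5 lower, adjusted p = 0.00743) and the cytosolic ribosomal protein genes (3 of 4 higher, 4 over the list alone, adjusted p = 0.0305). None of these 3 passed with an estimated correlation. The other 3 types in this contrast include the 2 rank 4 arrays, in which the T cell marker list averaged 8.27 and 8.11.

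Cytotoxic T cells carried the effector genes, although 1 of their 5 arrays did not. Of 14 cytotoxic and NK effector genes 13 were higher (14 over the list alone, adjusted p = 3.49e-15, and adjusted p = 0.0945 with an estimated correlation), with CD8A at 3.70 ± 0.65 log2, GZMH at 3.57 ± 0.62, CCL5 at 3.39 ± 0.51 and GNLY at 3.05 ± 0.50. The list averaged 8.18 in the rank 4 array and 10.56 to 11.10 in the other 4 cytotoxic arrays. Of 12 T cell markers 9 were higher (10 over the list alone, adjusted p = 6.69e-08, and adjusted p = 0.109 with an estimated correlation). Of 6 NK cell markers 4 were higher, with KLRD1 at 3.05 ± 0.43 and KLRF1 at 1.43 ± 0.21 (5 over the list alone, adjusted p = 0.00142, and adjusted p = 0.187 with an estimated correlation). Of 7 T cell receptor signalling genes 3 were higher (4 over the list alone, adjusted p = 0.00442, and adjusted p = 0.187 with an estimated correlation). NCAM1, which encodes CD56, was higher in monocytes (2.77 ± 0.15) and lower in cytotoxic T cells (-0.88 ± 0.15). The monocytes are among the 3 types averaged in the latter contrast, so their high level lowers that value. Immediate early genes were lower, with EGR1 at -1.41 ± 0.34 and FOSB at -1.35 ± 0.34 past the test (2 of 10, 4 over the list alone, adjusted p = 0.000773, and adjusted p = 0.0928 with an estimated correlation). Lower too were the inflammatory genes (2 of 8, 4 over the list alone, adjusted p = 0.00207, and adjusted p = 0.188 with an estimated correlation) and the MHC class II genes (2 of 4, 3 over the list alone, adjusted p = 0.00636, and adjusted p = 0.177 with an estimated correlation). The same was seen for granulocyte markers (2 of 8, 3 over the list alone, adjusted p = 0.0223, and adjusted p = 0.197 with an estimated correlation) and glucocorticoid-responsive genes, with SGK1 at -1.73 ± 0.13 (3 of 11, 4 over the list alone, adjusted p = 0.0308, and adjusted p = 0.307 with an estimated correlation). SGK1 was higher in monocytes, which are among the 3 types averaged here. The glucocorticoid-responsive list averaged 8.47 in the rank 4 array and 10.26 to 10.55 in the other 4. Its call was lost without that animal and with 18 arrays (adjusted p = 0.71). With 18 arrays the lower immediate early genes were 6 of 10 and the lower inflammatory genes 4 of 8. The B cell markers passed too (3 of 6 lower, adjusted p = 0.00797), though not with an estimated correlation. The effector genes (14 of 14 higher), T cell markers (10 of 12 higher) and T cell receptor signalling genes (4 of 7 higher) then passed with an estimated correlation (adjusted p = 0.0489 each), as did the MHC class II genes (adjusted p = 0.0497).

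B cells carried the B cell lists and the antigen presentation genes. Of 6 B cell markers 5 were higher (5 over the list alone, adjusted p = 1.35e-05, and adjusted p = 0.109 with an estimated correlation), with CD79B at 4.43 ± 0.57 log2, EBF1, a transcription factor that commits cells to the lineage, at 1.42 ± 0.19, BANK1 at 0.73 ± 0.08 and CD72 at 0.68 ± 0.13. All 4 measured MHC class II genes were higher, with HLA-DQB1 at 2.17 ± 0.46, HLA-DOB at 1.88 ± 0.32 and CD74 at 1.86 ± 0.50 (4 over the list alone, adjusted p = 0.000268, and adjusted p = 0.0877 with an estimated correlation). That list averaged 8.30 in the rank 4 B cell array and 10.69 to 11.42 in the other 4. Of 5 B cell receptor signalling genes CD79B and CD72 were higher (3 over the list alone, adjusted p = 0.00589, and adjusted p = 0.187 with an estimated correlation). Of 11 lineage transcription factors 8 were lower, mostly those of T cells and monocytes, with BCL11B at -2.19 ± 0.41 and CEBPB at -1.90 ± 0.40. In the same list EBF1 and BACH2 (1.19 ± 0.19) were higher (8 lower and 2 higher over the list alone, adjusted p = 0.000483, and adjusted p = 0.0311 with an estimated correlation). Lower were 8 of 12 T cell markers (11 over the list alone, adjusted p = 3.01e-08, and adjusted p = 0.103 with an estimated correlation) and 5 of 14 cytotoxic and NK effector genes (12 over the list alone, adjusted p = 1.57e-05, and adjusted p = 0.323 with an estimated correlation). So were 3 of 6 NK cell markers (4 over the list alone, adjusted p = 0.0184, and adjusted p = 0.315 with an estimated correlation) and 2 of 8 granulocyte markers (2 over the list alone, adjusted p = 0.0161, and adjusted p = 0.187 with an estimated correlation). The last were 3 of 11 glucocorticoid-responsive genes (3 over the list alone, adjusted p = 0.01, and adjusted p = 0.208 with an estimated correlation). The glucocorticoid-responsive call, in which the list averaged 8.49 in the rank 4 array and 10.28 to 10.43 in the other 4, was lost without that animal and with 18 arrays (adjusted p = 0.416). With 18 arrays 12 of 14 effector genes were lower, 11 of 12 T cell markers were lower and 4 of 5 B cell receptor signalling genes were higher. The T cell receptor signalling genes passed too (4 of 7 lower and 1 higher, adjusted p = 0.0203), though not with an estimated correlation. With an estimated correlation the T cell markers and the MHC class II genes then passed (adjusted p = 0.0489 each).

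The remaining 8 lists passed in no cell type with 20 arrays, and with 18 arrays only the cytosolic ribosomal protein genes did, in helper T cells (adjusted p = 0.0305). That call did not hold with an estimated correlation. Without rank 4 the same call was made (adjusted p = 0.0397), and without rank 3 the interferon genes passed in monocytes (adjusted p = 0.0481). Of 10 type I interferon genes 4 were higher in monocytes, with IFI6 at 1.24 ± 0.26 and IFI44 at 0.85 ± 0.22, and IFIH1, a sensor of viral RNA, was lower (5 and 1 over the list alone, adjusted p = 0.0852). Without rank 2 IFIH1 missed the threshold by limma (adjusted p = 0.079). The rank 1 animal stood apart, with IFI6 at 13.31 in its monocytes against 10.42 to 11.82 and IFI44 at 10.85 against 9.19 to 9.50, and without it the differences of these genes were 0.95 ± 0.24 and 0.74 ± 0.18. Of 4 plasma cell markers JCHAIN, the joining chain of secreted antibodies (1.38 ± 0.22), and MZB1 (1.25 ± 0.18) were higher in B cells (2 over the list alone, adjusted p = 0.119). Of 7 chemokine receptors and homing genes CXCR5, the receptor that guides B cells to follicles, was higher in B cells (1.45 ± 0.22) and CX3CR1 (-0.59 ± 0.17) and CCR2 (-0.34 ± 0.10) were lower (1 and 2 over the list alone, adjusted p = 0.667). In monocytes 1 of 7 platelet markers was higher, GNG11 at 1.46 ± 0.33 (1 over the list alone, adjusted p = 0.775), and 1 of 5 dendritic cell markers, FCER1A at 0.63 ± 0.18 (1 over the list alone, adjusted p = 0.79). Of 3 heat shock genes BAG3, a co-chaperone, was higher (0.76 ± 0.07) and HSP90AB1 lower (-0.65 ± 0.21) in monocytes (1 and 2 over the list alone, adjusted p = 0.854). Of 4 cytosolic ribosomal protein genes RPL13 (-0.59 ± 0.17) and RPL30 (-0.31 ± 0.08) were lower in monocytes (2 over the list alone, adjusted p = 0.272), where with 18 arrays all 4 were lower (adjusted p = 0.104). In helper T cells RPL13 was higher (0.55 ± 0.17, adjusted p of the list 0.17). None of 8 erythroid markers passed in any type by limma, over all probes or over the list alone, with adjusted p of camera from 0.627 to 0.957. With 18 arrays 3 erythroid markers were higher in B cells, and in monocytes 1 was higher and 1 lower. In monocytes 6 interferon genes, 3 dendritic cell markers and 2 platelet markers were then higher.

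Some lists without a call held strong members in both directions. Among 11 glucocorticoid-responsive genes in monocytes, SGK1, a kinase induced by the hormone, was higher by 4.79 ± 0.13 log2 and TSC22D3, another induced gene, was lower (-2.39 ± 0.62), so that the list median was -0.08, the mean 0.61 and the direction of the test up (adjusted p = 0.17). In helper T cells the same list had a median of 0.43 and a mean of 0.24 with a test direction of down (adjusted p = 0.854). Among the lineage transcription factors KLF4 (4.10 ± 0.30) and CEBPD (3.20 ± 0.08) were higher in monocytes and BCL11B lower (-2.65 ± 0.41), with a median of -0.76, a mean of 0.23 and a test direction of up (adjusted p = 0.74). The heat shock genes in monocytes had a median of -0.65 and a mean of -0.20 with a test direction of up, and the chemokine receptors and homing genes in B cells a median of -0.19 and a mean of 0.01 with a test direction of down. MHC class II genes in monocytes split too, with CD74 (3.41 ± 0.50) and HLA-DQB1 (1.87 ± 0.46) higher and HLA-DOB lower (-1.21 ± 0.32, adjusted p of the list 0.47). By limma HLA-DOB missed the threshold without rank 3 (adjusted p = 0.0651) and without rank 5 (adjusted p = 0.0648).

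Along dominance rank no probe passed in any cell type, and the genes with the smallest p are given with their slopes. In helper T cells CLINT1, a vesicle coat adaptor, had a slope of -0.25 ± 0.03 log2 per rank step, ORAI1, a calcium channel of T cell activation, of -0.21 ± 0.03 and METTL22 of 0.23 ± 0.03, with the smallest adjusted p at 0.77. In cytotoxic T cells SMARCD1, a chromatin remodelling subunit (-0.37 ± 0.06), ST3GAL5, a ganglioside synthase (-0.34 ± 0.07), and AQR, a splicing helicase (-0.29 ± 0.07), came first, with an adjusted p of 0.943. In monocytes MT1G, a metal-binding metallothionein, had a slope of -0.75 ± 0.09, with levels of 11.97, 11.87, 11.05, 9.68 and 9.29 at ranks 1 to 5, followed by BEX3 (0.20 ± 0.03) and CTSA (-0.23 ± 0.03), a lysosomal protease (adjusted p = 0.647). In B cells SMARCD1 (-0.51 ± 0.08), SMAP2 (-0.28 ± 0.06) and BTLA, an inhibitory receptor (0.36 ± 0.08), came first (adjusted p = 0.955). In the mean of the 4 types these were SMARCD1 (-0.34 ± 0.05), UGCG (-0.30 ± 0.05) and BNIP2 (-0.27 ± 0.05) (adjusted p = 0.966). By limma 0 probes had an adjusted p under 0.05 in each fit, against 407, 53, 471, 74 and 192 at an unadjusted p under 0.05. Without the 2 rank 4 arrays the counts stayed at 0, with 918, 720 and 842 probes at an unadjusted p under 0.05 in cytotoxic T cells, B cells and the mean. With array weights limma called 0 probes in helper T cells, 1339 in cytotoxic T cells, 822 in monocytes, 1340 in B cells and 4005 in the mean. Pooled slopes called MT1G in monocytes and SMARCD1 in B cells.

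Of the 4 genes chosen in advance for rank, PTGS2 had the steepest slope. In monocytes it stood at 10.60, 9.66, 10.76, 11.39 and 11.72 at ranks 1 to 5, a slope of 0.40 ± 0.14 log2 per step that did not pass after adjustment. In the other types its slope lay between 0.01 ± 0.03 in helper T cells and 0.02 ± 0.07 in B cells. Its levels in those types were 7.67 to 8.04, near the floor of the arrays, so a slope could hardly show there. With 18 arrays its slope was -0.02 ± 0.03 in cytotoxic T cells and -0.01 ± 0.03 in B cells. NR3C1, the glucocorticoid receptor, had slopes of -0.09 ± 0.05, -0.11 ± 0.09, -0.23 ± 0.10 and -0.13 ± 0.09 in helper T cells, in cytotoxic T cells, in monocytes and in B cells, none of which passed. With 18 arrays they were -0.05 ± 0.03 in cytotoxic T cells and -0.09 ± 0.05 in B cells. CXCR2, a chemokine receptor, and NFATC1, a transcription factor of lymphocyte activation, had slopes of -0.02 ± 0.09 and -0.01 ± 0.04 in monocytes and of 0.02 ± 0.02 and 0.04 ± 0.04 in helper T cells. In cytotoxic T cells they were 0.13 ± 0.15 and 0.06 ± 0.08 and in B cells 0.16 ± 0.17 and 0.07 ± 0.06, with CXCR2 at 9.14 and 9.23 in the 2 rank 4 arrays. With 18 arrays the slopes of CXCR2 were 0.02 ± 0.03 in cytotoxic T cells and 0.03 ± 0.03 in B cells. Both genes lay between 7.83 and 8.14 in helper T cells, near the floor as well.

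Of the 8 lists followed along rank, none of the 40 tests passed. In monocytes the 3 heat shock genes all had negative slopes, with a list slope of -0.10 ± 0.02 log2 per step (exact permutation p = 0.0167, the smallest that 5 animals allow, adjusted p = 0.667). All 10 immediate early genes had positive slopes there, with a list slope of 0.16 ± 0.05 (exact permutation p = 0.0667, adjusted p = 0.718). All 10 type I interferon genes had negative ones, with a list slope of -0.25 ± 0.14 (exact permutation p = 0.183). The interferon list averaged 9.80 in the rank 1 monocyte array and 8.43 to 8.75 in the other 4. In monocytes the slopes of the other lists were 0.12 ± 0.07 for monocyte markers, -0.06 ± 0.02 for cytotoxic and NK effector genes, -0.04 ± 0.02 for platelet markers, 0.02 ± 0.05 for glucocorticoid-responsive genes and -0.01 ± 0.07 for inflammatory genes. In B cells the inflammatory genes had a slope of -0.23 ± 0.10 (exact permutation p = 0.133). With 20 arrays 1 of the 40 tests had an unadjusted p under 0.05, and no member of a list passed, over all probes or over the list alone. With 18 arrays 2 of the 40 tests had such a p, the second being the platelet markers in the mean of the 4 types (slope of -0.02, n = 4, exact permutation p = 0.0417, adjusted p = 0.667). In cytotoxic T cells 1 heat shock gene then passed over the list alone and none over all probes.

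The slope on rank differed between cell types for MT1G alone. In monocytes it fell by 0.75 log2 per rank step, and its slopes in helper T cells, cytotoxic T cells and B cells were -0.02, -0.02 and 0.00 (adjusted p = 0.0247). Its levels in those 3 types were 7.98 to 8.49, near the floor of the arrays. MT2A, another metallothionein, had the next smallest p, with monocyte levels of 14.31, 14.10, 13.45, 11.71 and 11.62 at ranks 1 to 5, and did not pass (adjusted p = 0.32). Its slope was -0.78 ± 0.12 there and -0.05, -0.09 and -0.05 in helper T cells, cytotoxic T cells and B cells. NRP2, a co-receptor for semaphorins, followed (adjusted p = 0.992). By limma 1 probe passed, with 113 at an unadjusted p under 0.05. With 18 arrays 2 passed, MT1G (adjusted p = 0.0201) and the B cell gene FCRLA (adjusted p = 0.0393, slope of 0.31 ± 0.04 in B cells). Leaving out the animal of rank 1, 2, 3 or 5 gave 0 by limma, with 11, 24, 82 and 1548 probes at an unadjusted p under 0.05. Leaving out rank 4 gave 4.

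**Figure D3:**
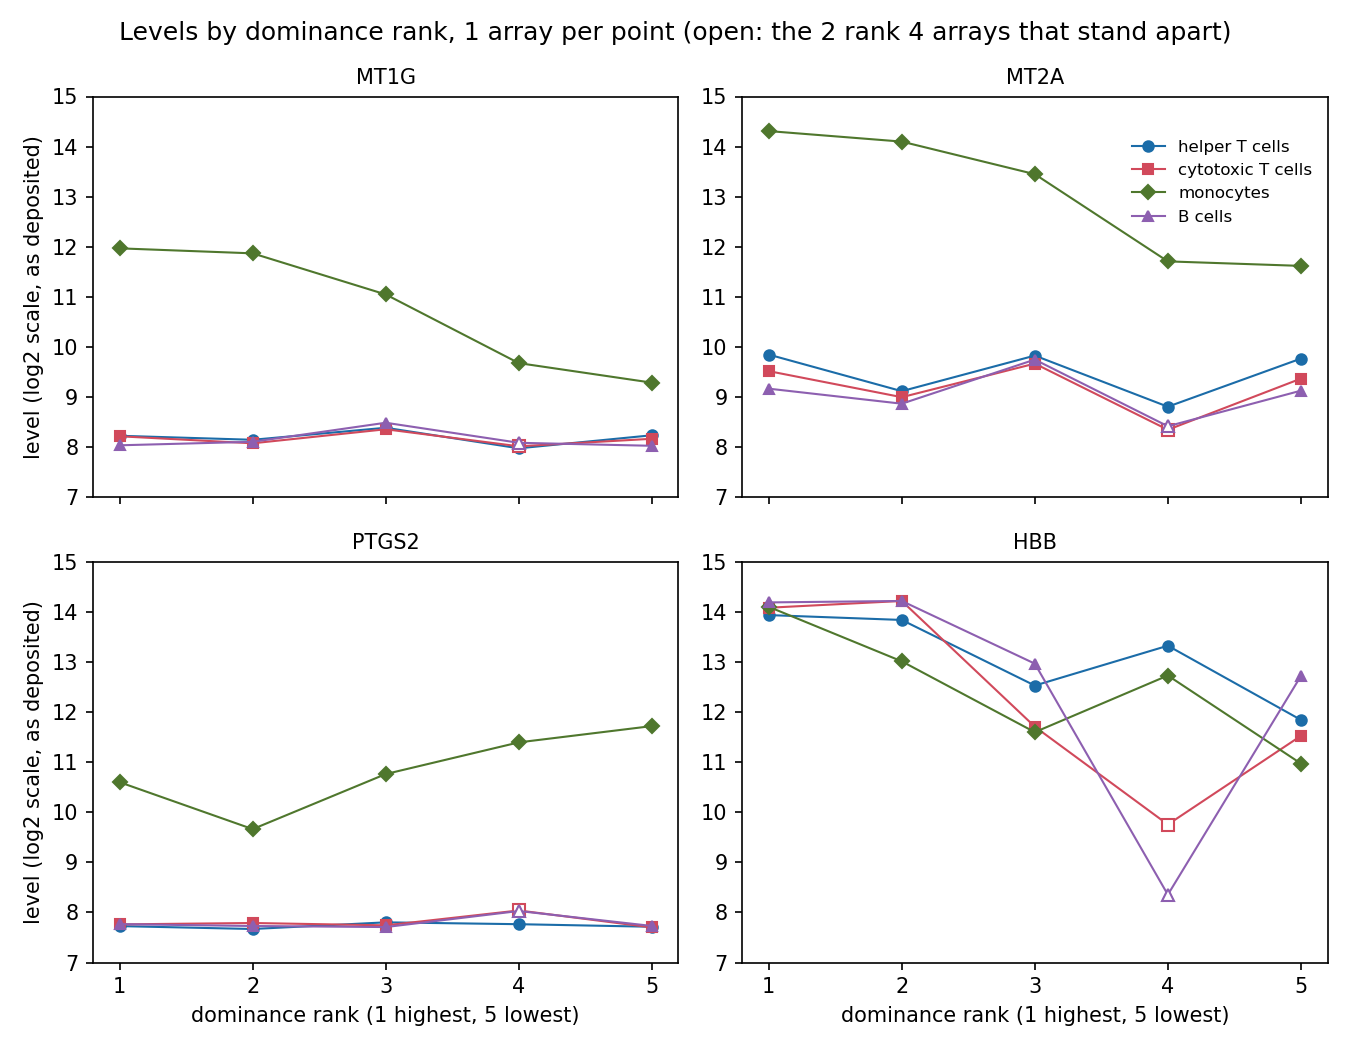
Levels (log2) of MT1G, MT2A, PTGS2 and HBB against dominance rank (1 high, 5 low), with 1 line per cell type, 1 animal per rank and open symbols for the rank 4 cytotoxic T cell and B cell arrays. In monocytes MT1G goes from 11.97 at rank 1 to 9.29 at rank 5, and HBB in helper T cells goes from 13.93 to 11.84 with 12.53 at rank 3 and 13.32 at rank 4.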

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

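Dixon's gap, the test of slopes between cell types and the counts over other splits and orders were planned, and the other tests in this part, including the counts within animals and the orders at unadjusted p, were chosen only after the result they bear on had been seen. The orders with array weights were chosen after the counts in the real order had been seen and before any other order was run.

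In the rank 4 animal the cytotoxic T cell array had a median correlation of 0.167 with the other cytotoxic arrays and the B cell array 0.180 with the other B cell arrays, where the rest lay between 0.928 and 0.967. Each stood out because its gap to the nearest of 5 arrays was large for the range of the group (Dixon's gap, which chance exceeds in about 1 of 20 groups). The same measure singled out the mean of 12 of 24 gene lists in cytotoxic T cells, all by the rank 4 array, and 10 of 24 in B cells, 9 of them by the rank 4 array and plasma cell markers by rank 2 (8.58 against 8.85 to 8.96). In helper T cells it singled out 0 of 24, where chance gives 1.2. Of 28 named genes it singled out 2 in helper T cells, 7 in cytotoxic T cells, 2 in monocytes and 6 in B cells, and the rank 4 array was the one far out in 0, 7, 0 and 4 of them. The 2 arrays were not low for every probe that is bright in the others. HBA2 was at 14.66 and 14.19 beside HBB at 9.76 and 8.35, although both globins were between 10.97 and 14.22 in the other 18 arrays. The columns share 1 distribution, so some probes must be bright in any array, and such values do not show abundant RNA in these 2.

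For these 2 arrays, 3 technical explanations were tested. A random order of the probe values is argued against by their correlation with the mean of the other 18, 0.193, above the highest of 1000 reshuffles of the probes (0.0446). Intact RNA of another macaque tissue is argued against by the ribosomal protein probes, 4 of 5 of which fell by over 2 log2 in both arrays, such as RPS9 from a mean of 14.06 to 7.89 and 7.99. This rests on few genes, with 2 of the 4 probes for RPS9 and the others for RPL23 and RPL10A. The fifth, RPL30, stayed at 14.45 and 14.57 against a mean of 14.43. The cytosolic ribosomal protein list averaged 10.97 in the cytotoxic array (others 11.67 to 12.17) and 10.71 in the B cell array (others 11.51 to 12.20). Too little RNA cannot be told apart from other causes, since 2 probes of a gene correlated at 0.229 over all genes with several probes (highest reshuffle 0.133), which a residue of the cells' own RNA would also give, and at 0.204 over the 144 genes dim in the other 18 (6 of 1000 reshuffles as high, highest 0.231). A failed hybridisation, probes read at wrong positions in part, or another source of RNA stay open as well, and no biological explanation was tested, since the design holds no second array of this animal and type.

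In monocytes 3 of 24 lists held an array far from the other 4, where chance gives 1.2. MHC class II genes were at 9.36 in the rank 4 animal against 10.15 to 10.27, through HLA-DQB1 at 8.35 against 11.50 to 11.71. Lineage transcription factors were at 9.61 in the rank 1 animal against 9.70 to 9.74. Type I interferon genes were at 9.80 in the rank 1 animal against 8.43 to 8.75, with HERC5 at 11.24 against 7.95 to 8.63 and ISG15 at 10.30 against 7.88 to 8.58. No explanation was tested for these 3.

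MT1G stood out because its slope on rank differed between the cell types (adjusted p = 0.0247), falling in monocytes alone among the 4. In the other types it lay at 7.98 to 8.49, near the floor of the arrays, so a fall could hardly show there. The component that parts ranks 3 and 5 from ranks 1, 2 and 4 is argued against, since rank 3 lay above rank 4 by 1.38 log2 for MT1G and 1.74 for MT2A. A falling share of monocytes is argued against by the monocyte marker list, whose slope was 0.12 ± 0.07 per step while MT1G had -0.75. Rank itself cannot be told apart from chance, since 11 of 60 orders of the ranks gave at least 1 probe whose slope differs, with 12 at most against 1 in the real order, although no other order gave MT1G a slope as steep (exact permutation p = 0.0167, the smallest that 5 animals allow, for a gene picked by its p). A change of metallothioneins with rank in monocytes therefore may be no more than a difference between these 5 animals, their social groups or their handling.

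Apart from the 2 arrays of the rank 4 animal, the first principal component within cell types took 46.9% of the variance and placed each animal alike in every type. Its scores at ranks 1 to 5 were -7.38, -15.91, 13.14, -5.48 and 15.63 in helper T cells and -10.50, -14.38, 15.97, -5.51 and 14.42 in monocytes. A steady change with rank is argued against, since rank 4 minus rank 3 was -18.62 in helper T cells and -21.48 in monocytes, where such a change has a positive sign. Red blood cell RNA stays open. The erythroid list held 1.5% of the squared loadings, but its 8 genes are too few among all probes for this share to decide. Its mean was lowest at ranks 3 and 5, as on the component. At ranks 1 to 5 it was 9.89, 9.88, 9.17, 9.53 and 9.09 in helper T cells. In monocytes it was 10.15, 9.63, 9.07, 9.43 and 9.03. A difference in processing between days, or between animals and their groups, stays open as well, and no biological explanation other than rank was tested.

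Other splits of the 10 arrays of 2 types into 5 and 5 were counted, 100 for each contrast. As many probes as in the real split were found in 1 split, the real one, for helper against cytotoxic T cells (22, highest other 17), helper T cells against monocytes (2591, 1537), helper T cells against B cells (671, 304), cytotoxic T cells against monocytes (2361, 1429) and monocytes against B cells (2086, 978). For cytotoxic T cells against B cells 2 splits did, with 462 in the real split and 467 in the highest other. Over splits that ignore the animals, the share was under 0.05 in each of these 6. Of the 100 splits, 85 to 87 put both arrays of some animals on 1 side and so break the pairing that the fit uses. They cannot exclude chance for a paired fit. The splits that part all 5 animals as the real one does are too few for a share under 0.05. As many probes were found in 1 of 14, 1 of 14, 1 of 15, 1 of 14, 2 of 13 and 1 of 14 of them, and the highest other was 0, 0, 304, 1429, 467 and 978, in the order helper against cytotoxic T cells, monocytes and B cells, cytotoxic T cells against monocytes and B cells, and monocytes against B cells. In the last 4 it exchanged only the arrays of rank 4, so that the odd array changed sides.

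Other divisions of the 20 arrays into 4 groups of 5 gave as many enriched probes in 1 of 100 for helper T cells (5, highest other 0), 2 for cytotoxic T cells (1, highest other 1), 1 for monocytes (360, highest other 0) and 1 for B cells (48, highest other 0). In all 4 types the share was under 0.05. These divisions cannot exclude chance, since they ignore the animals, mix monocytes with lymphocytes and so widen the spread within groups. Divisions that exchange arrays within animals gave as many in 2, 2, 1 and 1 of 100, with 36, 54, 24 and 20 in the highest other. In helper and cytotoxic T cells these are several times the real 5 and 1, which points to a structure of the samples. In both, the group held the monocyte arrays of ranks 1, 2, 3 and 5 and an odd array of rank 4, so the high counts follow the monocytes under another label.

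Orders of the 5 ranks were counted over all 60 that differ. By limma the real order gave 0 probes in each of helper T cells, cytotoxic T cells, monocytes, B cells and the mean of the 4 types, with 407, 53, 471, 74 and 192 at an unadjusted p under 0.05. All 60 orders give at least 0, so these counts leave nothing for the orders to test. The highest other gave 417, 0, 662, 0 and 0, which points to a structure of the samples. In every order that called a probe in helper T cells or monocytes the animals of ranks 3 and 5 were placed at one end, as on the principal component. At an unadjusted p under 0.05 as many as in the real order were found in 18, 30, 16, 36 and 33 of 60 orders, with 1841, 876, 2082, 1012 and 1422 in the highest other. With array weights, as many as the real 0, 1339, 822, 1340 and 4005 were found in 60, 4, 25, 7 and 2 of 60 orders, with 2695, 2466, 2927, 4248 and 4305 in the highest other. The real 0 in helper T cells leaves nothing to test, and chance is not excluded for cytotoxic T cells, monocytes and B cells. For the mean of the 4 types 2 of 60 is under 0.05, but its weights ran from 0.03 at rank 4 to 13.78 at rank 5, so that count rests unevenly on the animals, and 28 of the 60 orders called probes.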

How the results depend on the processing

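The fits without the rank 4 cytotoxic T cell and B cell arrays were chosen after seeing the data, and all other alternatives before. The comparisons of named genes cover those called in the planned fits as enriched or between helper and cytotoxic T cells. None of these genes and no called list changed direction under any alternative run. Rank slopes of named genes were not among these comparisons, and some changed sign. Without the rank 4 arrays the slope of PTGS2 went from 0.01 to -0.02 in cytotoxic T cells and from 0.02 to -0.01 in B cells. Of the comparisons of named genes 379 kept their side of the threshold and 84 lost the call; of those of gene lists 1040 kept it, 45 lost a call, 13 gained one and 54 uncalled ones changed sign; of the counts 189 stayed within 1.5 times and 85 did not.

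Without the rank 4 cytotoxic T cell and B cell arrays the pairwise counts were 193 for helper against cytotoxic T cells, 4488 for helper T cells against monocytes, 1839 for helper T cells against B cells, 4328 for cytotoxic T cells against monocytes, 1819 for cytotoxic T cells against B cells and 3914 for monocytes against B cells. Probes enriched in helper T cells, cytotoxic T cells and B cells were 8, 22 and 76, and 2 had rank slopes that differ between cell types. Both the residual spread and the means of these types change when the 2 arrays are removed, and the cause was not tested. Array weights gave 621, 4249, 2268, 4112, 2262 and 3534 in the same order, enriched counts of 10, 22 and 76, and rank slopes in 1339 probes in cytotoxic T cells, 822 in monocytes, 1340 in B cells and 4005 in the mean of the 4 types. For these rank slopes other orders of the ranks called as many or more.

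Leaving out each animal in turn gave 1 to 140 probes for helper against cytotoxic T cells, 1873 to 4220 for helper T cells against monocytes, 281 to 1744 for helper T cells against B cells, 1616 to 4270 for cytotoxic T cells against monocytes, 69 to 1808 for cytotoxic T cells against B cells and 1290 to 3847 for monocytes against B cells. Enriched counts ran from 0 to 8 in helper T cells, 0 to 22 in cytotoxic T cells and 14 to 76 in B cells, and stayed within 330 to 368 in monocytes. Rank slopes that differ between cell types ran from 0 to 4. Each highest count but the 368, which is without rank 3, is without rank 4. The lower ones have fewer arrays with the 2 odd ones still among them.

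Without the replicate block the count for helper T cells against B cells was 427 and cytotoxic T cells had 2 enriched probes, and AXIN2 (1.18, also as an enriched gene), KLHL5, TRAF3IP2, KLF8 and DUSP22 lost their call for helper against cytotoxic T cells. With the replicate block as a random effect helper against cytotoxic T cells gave 47 probes, and 9 and 7 were enriched in helper and cytotoxic T cells. The cause was not tested. With only the 10 arrays of the 2 types and the replicate block the 6 counts were 0, 4068, 267, 1241, 54 and 926, where the spread comes from 10 arrays alone; the 0 is by limma, with 395 at an unadjusted p under 0.05.

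Leaving out the dimmest 25% of probes or keeping 1 probe per gene gave 13 and 13 probes for helper against cytotoxic T cells, and the latter 2 enriched in helper T cells, with fewer probes tested. Both lost TRAF3IP2, and the former also SOS1 and KLF8. The former left 35 gene list calls. It lost the helper T cell markers (adjusted p = 0.545) and the cell cycle genes (0.172) in helper T cells, the cell cycle genes in monocytes (0.056) and the B cell markers in B cells (0.12), and gained the T cell receptor signalling genes in B cells (0.0388). Moderation with trend and robust gave 2 enriched in cytotoxic T cells and lost DUSP22, and the cause was not tested. No minimum difference gave 18, 2, 817 and 108 enriched probes in helper and cytotoxic T cells, monocytes and B cells, by its construction. Pooled slopes called 1 probe in monocytes, MT1G (-0.75), and 1 in B cells, SMARCD1 (-0.51), with the spread taken over all cell types. An estimated correlation left 8 of the 38 gene list calls. Of the slopes of lists on rank 397 kept their sign and 43 changed it, with no call in any alternative.

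Normalizing again by 3 other methods moved values by at most 4.57e-05, 0 and 0.000183 and changed 0 counts, since the columns already share 1 distribution, so these 3 tests decide nothing. An offset of 50 before the logarithm was not run, since the values are already on a log scale. The median of the values, 8.39, lies close to their floor, so differences among dim probes are limited by the background of the arrays.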

Other observations

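The shared patterns and the globin and monocyte values in this part were looked at only after the data had been seen, and no explanation is offered for them.

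Some genes were shared by 2 or 3 cell types rather than enriched in 1. Both T cell types stood above monocytes and B cells in 44 probes, among them GZMH, a granzyme (by at least 3.90 log2), IL7R, the interleukin 7 receptor (2.99), CD3D (2.85), BCL11B, a transcription factor of T cell commitment (2.82), and LAT, an adaptor of the T cell receptor (2.44). All 3 lymphocyte types stood above monocytes in 97 probes, with the histone gene H4C3 (2.58), GRK5, a receptor kinase (2.31), and ETS1, a transcription factor of lymphocytes (2.16). Monocytes and B cells stood above both T cell types in 32 probes, with the antigen presentation genes HLA-DRB4 (3.56), CD74 (3.15) and HLA-DQB1 (2.84), the transcription factors HHEX (2.95) and EGR1 (2.57), and CD86, a ligand of T cell co-stimulation (2.18). Without the 2 arrays of the rank 4 animal these counts were 77, 193 and 62.

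Globin transcripts were abundant in the sorted cells and varied between animals. HBB was at 13.93, 13.84, 12.53, 13.32 and 11.84 at ranks 1 to 5 in helper T cells, with a slope of -0.47 ± 0.14 log2 per step there and -0.65 ± 0.19 in monocytes, neither of which passed (adjusted p = 0.77 and 0.647). HBA2 in helper T cells was at 13.54, 13.52, 11.40, 12.56 and 11.52. In both genes rank 4 lay above rank 3.

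Some monocyte transcripts were lower at ranks 3 and 5 than at the other ranks. CTSL, a lysosomal protease, was at 14.45, 14.43, 10.61, 13.60 and 10.30 in the monocytes of ranks 1 to 5, BASP1 at 13.59, 13.39, 10.50, 13.07 and 10.40, and JARID2, a chromatin regulator, at 12.49, 12.72, 9.83, 11.95 and 9.90. CD14 went the other way, at 12.43, 12.14, 14.16, 12.48 and 13.71.

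Among the metal-responsive genes that were measured beside MT1G and MT2A, the zinc exporter SLC30A1 had a slope of -0.02 ± 0.05 log2 per rank step in monocytes, MTF1, the transcription factor that induces metallothioneins, of 0.08 ± 0.05 and MT1X, near the floor of the arrays, of -0.06 ± 0.05. None of them passed, and they were chosen after the slope of MT1G had been seen.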
